A study of Sus scrofa with 19 samples.

How the data were processed

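Gene expression was measured in the endometrium, the lining of the uterus, of crossbred gilts (young female pigs, Sus scrofa) aged 8 months. Per the labels, both uterine horns were cannulated on days 8 to 9 of the cycle and infused at intervals of 4 h over a period of 24 h, which fell on days 11 to 12 from the start of oestrus. In 6 treated gilts, a horn chosen at random received prostaglandin E2 (PGE2, 200 µg per infusion) together with estradiol (E2, 33.3 µg per infusion), and the other horn received the vehicle (5 mL of saline with 1% ethanol) as placebo. In 4 control gilts, both horns received placebo. The series holds 19 arrays: 6 of hormone horns, 5 of the placebo horns of treated gilts, and 8 of control gilts, 4 marked L and 4 marked P. The labels do not say what L and P stand for. All 5 placebo horns were marked L and 5 of the 6 hormone horns were marked P, and for gilt 40 only the hormone horn, marked L, was analysed here. The endometrium of pregnant gilts or of gilts given estradiol alone, which the title of the series brings up, was not analysed here.

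Per the labels' protocols, total RNA was isolated with TRIzol, and 0.5 µg was amplified and labelled with Cy3 for one-colour Agilent arrays. Per the file headers, the deposited scanner files hold linear intensity values per spot, made by Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. The intensity used here, the processed signal in the deposited files, had been background-subtracted and spatially detrended by Feature Extraction within each array, per the file headers, with no scaling between arrays. The authors' deposited value table holds values on a log2 scale for the same arrays (r from 0.996 to 0.999 with the log2 scanner values of the same array). Its medians per array were 7.72 to 7.83. How the authors normalized or centred that table is not given in the sources used here, and it served as an alternative only.

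Each array had 45220 spots, of which 43803 were not controls. Between 79.1% and 88.4% of these were well above background, the 75th percentile of the processed signal was 594 to 978, 19 to 155 spots per array carried an outlier flag, and 0 were saturated. Control spots and values with an outlier flag (891 among the tested probes) were left out and spots of the same probe were averaged. Values were log2 of the processed signal minus the log2 of the array's 75th percentile, so a value of 0 marks the brightness of that percentile. The 39072 probes well above background on at least 4 arrays were tested.

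Arrays with the same gilt number in the labels came from the same animal. Their deviations from the group means were correlated (0.336 to 0.795 for hormone and placebo horns, and 0.403 to 0.627 for the horns of control gilts), above those with any other gilt (at most 0.113 and 0.0181). Taking deviations from group means itself lowers the correlations with other gilts. Both horns of a gilt lay on the same slide, so a correlation within gilts cannot be told apart from one within slides. The model therefore held the 4 groups and the gilt as a random block (limma 3.58.1 with duplicateCorrelation from statmod 1.5.0 in R 4.3.3; correlation within a gilt 0.536; eBayes with trend). Tests were two-sided with Benjamini-Hochberg adjustment over probes, and a probe passed at an adjusted p under 0.05. Comparisons against control gilts used the mean of the groups marked L and P. They set gilts against gilts, while the fit counts arrays and gives all probes the same correlation within a gilt. Their adjusted p can therefore be too small for probes that vary much between gilts. On simulated data with the real spread and 200 probes per set changed, a difference of 1 log2 unit was recovered for 74% of probes between the horns of a gilt, for 63.5% in hormone horns against control gilts (change in the hormone horn only), and for 58% in placebo horns against control gilts, over 39072 probes each. At 2 log2 units the shares were 97.5%, 93.5% and 87.5%. These shares hold for the number of probes changed in the simulation, which also gave every probe the same correlation within gilts. Between horns the simulation called 364 probes, against 1 in the real data, where the adjustment was therefore stricter. The 74% thus overstates recovery in the real comparison between horns.

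Gene symbols came only through RefSeq accessions in the scanner files, matched without version to the reference table of Sscrofa11.1. Of 43603 probes, 6876 matched 1 gene, 6731 of them a symbol that is not a placeholder (3099 symbols), and 36727 had no symbol here. For each gene, the probe with the highest mean signal over the 19 arrays was used, which gave 2986 genes. No coordinates were used.

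The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Named genes are the 10 largest rises and the 10 largest falls per comparison among genes that passed, the up to 3 members of each list with the smallest p between the horns of a gilt, and 14 genes of interest where measured (4 of these, PTGER2, PTGER4, HPGD and FGF7, were not measured by a named probe). A few further list members are named as examples chosen after their values were seen: CEBPB, RBP4, LCN2, TIMP2, SLPI, TREM1, PGLYRP1, NIFK, MUC4 and SGK1. The 28 gene lists held pathways and cell type markers, and 26 had the minimum of 3 measured members. They were tested with cameraPR on the moderated statistics (inter-gene correlation preset at 0.01, adjusted over lists within a comparison), with an estimated correlation and fry as alternatives, and members were also adjusted over the list alone. Some members were matched through synonyms in the reference table: NIFK, which the table lists with the synonym MKI67 and which is not a cell division marker itself, counts in the cell division list, and CTSV, CYP51 and HSP70.2 stand for CTSL, CYP51A1 and the HSPA1 genes.

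Alternatives covered the gilt as a fixed block or left out, the mean of both horns of each control gilt, only the groups compared, quantile and median scaling, the authors' value table, stricter and no filters on dim probes, the horn mark as a term or as a correction, the slide as a fixed term, array weights, a minimum fold of 1.5, eBayes without trend, and each gilt left out in turn. Normexp could not be run as planned because no mean signal column was held, so it was run on the median signals (offset 50). The files gave 9 slides, 8 of which held the arrays of 1 gilt each, and 3 scan days, each with both treated and control gilts. Exact permutation tests across gilts were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.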

Results

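Endometrial RNA of 10 gilts was profiled on 19 one-colour arrays, with 6 hormone horns, 5 placebo horns of the same treated gilts, and 8 horns of 4 control gilts. Hormone horns had received PGE2 and E2 for 24 h, a period in which signals of an early conceptus would reach the uterus in a pregnant animal. On each array 79.1% to 88.4% of spots were well above background. The 75th percentile of the signal was 594 to 978, lowest in the hormone horn of gilt 36. The first principal component (33.7% of variance) placed all 8 control horns at one end and both horns of gilt 47 (155 and 133) at the other. On the second component (13.8%) the hormone horn of gilt 36 lay apart at -147. Markers of immune cells were far higher in both horns of gilt 47 than in the other treated gilts: in the hormone and placebo horn the median T and natural killer cell marker was 2.46 and 2.38 log2 units above control gilts, the B cell marker 3.08 and 3.32, and the macrophage marker 2.50 and 2.72. The T and natural killer cell median of the other treated gilts lay between -0.04 and 0.74. The scan day and annotation class terms, normexp on median signals, the fits without the hormone horn of gilt 36, and the permutation of horn differences were chosen after results had been seen.

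**Figure D1:**
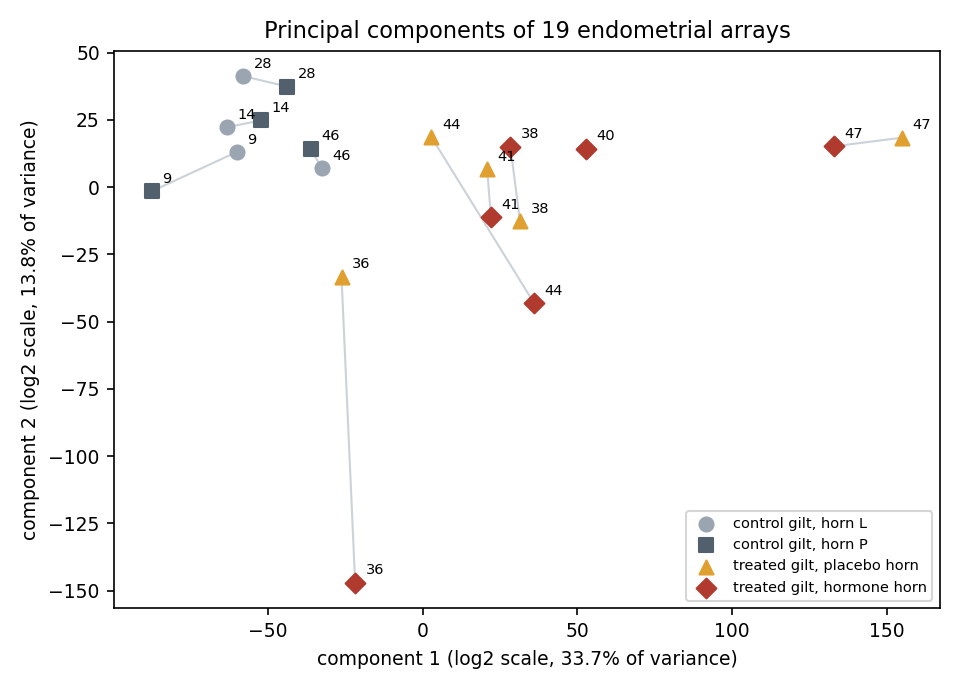
Scores of the 19 arrays on the first 2 principal components of log2 signal (component 1, 33.7% of variance; component 2, 13.8%), 1 point per uterine horn with its gilt number, lines joining the horns of a gilt. All control horns lie left of every treated horn, gilt 47 lies far to the right (155 and 133), and the hormone horn of gilt 36 lies at -147 on component 2.

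The comparison of hormone horns with control gilts asked how endometrium given PGE2 and E2 differed from endometrium of animals that never received them. S100A8 and S100A9, calcium-binding proteins abundant in neutrophils, rose by 6.41 ± 1.15 and 5.65 ± 1.06 log2 units (difference ± SE, 6 hormone horns against 8 control horns; limma adjusted p = 0.00358 and 0.00442). DMBT1, a secreted mucosal glycoprotein, rose by 5.44 ± 0.59 (43.3-fold, adjusted p = 0.000484), and the acute phase gene SAA3 rose by 5.34 ± 0.99 (adjusted p = 0.00414). S100A12, CHI3L1, the peptide transporter SLC15A1, STEAP1, SERPINA3-2 and GGT1 rose by 4.79, 4.14, 3.75, 3.32, 3.22 and 2.91. Among the largest falls were the antimicrobial genes REG3G (-3.69 ± 0.69, adjusted p = 0.00425) and DEFB1 (-2.80 ± 0.55, adjusted p = 0.00537), GDF15 (-2.53) and RGS4, a regulator of G protein signalling (-2.48 ± 0.39, adjusted p = 0.00226). OPTC, C1QTNF3, PNPLA3, CELA2A, FXYD2 and BAALC fell as well (-4.70, -3.71, -3.19, -2.81, -2.58 and -2.58). Each of these 20 genes kept its direction whichever gilt was left out, a weak check for the largest differences of the same arrays, and 15 still passed every time. SERPINA3-2, OPTC, C1QTNF3, CELA2A and FXYD2 did not (highest adjusted p 0.134, 0.108, 0.134, 0.0814 and 0.113).

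In all, 4591 of 39072 probes passed (limma, adjusted p under 0.05), 2679 higher and 1912 lower, with a median size of 0.811 log2 units among them. Named genes mostly rose, 569 symbols against 88, and symbols were known only for probes that the array identifies by RefSeq. Of RefSeq probes 1139 passed as higher and 159 as lower, whereas of probes identified by an assembled contig 256 were higher and 954 lower. Quantile normalization called 4630 probes with 50.9% higher, and normexp on median signals 3540 with 48.3% higher, against 58.4% here. With scan day as a term 5102 probes passed, and within the scan days, which held 1 or 2 control gilts each, 887, 6 and 0 passed (limma). Without the arrays of scan day 1, 2 or 3, 2736, 3 and 3751 passed (limma), and day 2 held 2 of the 4 control gilts. The count fell to 1465, 1627, 1782 and 2899 without gilts 14, 28, 9 and 44, was 2525 with the horns of each control gilt averaged and 6965 without the gilt block, and was 0 (1382 at an unadjusted p under 0.05) with the difference between RefSeq and contig probes per array as a term, a measure that itself separated treated from control gilts.

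Genes of cell division rose as a group in hormone horns, with a list median of 2.91 above control gilts in gilt 47 and 0.728 to 1.39 in the other gilts. Of 9 measured members 8 rose, also when adjusted over the list alone, and the median was 1.35 log2 units (cameraPR adjusted p = 6.67e-07; adjusted p = 0.223 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, rose by 2.70 ± 0.43 (adjusted p = 0.00232), from a mean of -2.22 ± 0.60 (SD over 4 control gilts) to 0.48 ± 0.85 (SD, n = 6). CCNB1, its cyclin partner, rose by 1.35 and BIRC5 by 1.27. NIFK, in the list through a synonym only, rose by 0.75 (adjusted p = 0.0235). In the list of oxygen lack and glycolysis 4 of 7 members rose (5 adjusted over the list alone; median 0.91, adjusted p = 0.00705; adjusted p = 0.356 with an estimated correlation), among them PGK1 (0.91), PDK1 (0.85) and ADM, which encodes a vasodilator peptide (2.57). In the list of endoplasmic reticulum chaperones 6 of 11 rose (7 adjusted over the list alone; adjusted p = 0.016; adjusted p = 0.365 with an estimated correlation), including SEC61A1, part of the channel for protein import (0.84). In the extracellular matrix list 6 of 14 rose, or 8 adjusted over the list alone (cameraPR adjusted p = 0.0272, and adjusted p = 0.365 with an estimated correlation). COL1A2 was at 0.75, COL5A1 at 0.82 and the cross-linking enzyme LOX at 1.02, and none of these passed without control gilt 9, 14 or 28. COL5A1 did not pass without treated gilt 36, 38 or 44 either, nor LOX without treated gilt 36, 38, 40 or 47.

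The list of uterine secretory products shifted upward with 4 of 19 members passing (8 adjusted over the list alone; adjusted p = 0.0411; adjusted p = 0.365 with an estimated correlation): the retinol carrier RBP4 (1.13), LCN2 (2.39) and the protease inhibitors TIMP2 (1.16) and SLPI (2.44). Endothelial markers rose in 3 of 5 cases (4 adjusted over the list alone; adjusted p = 0.0411; adjusted p = 0.419 with an estimated correlation), with VWF at 0.79 and ENG at 0.64, neither of which passed without control gilt 14. Macrophage and dendritic cell markers rose in 3 of 13 cases (4 adjusted over the list alone; adjusted p = 0.0327; adjusted p = 0.634 with an estimated correlation). LYZ, which encodes lysozyme, rose by 2.54, and the list's median per hormone horn was 2.50 above control gilts in gilt 47 and 0.07 to 1.00 in the other gilts. Neutrophil markers had a median of 2.01, but the list did not pass (adjusted p = 0.0838) and 3 of 8 members, the S100 genes above, rose. Among the other members TREM1, well above background on 9 arrays only, had 2.66 (adjusted p = 0.128) and PGLYRP1 -1.39 (adjusted p = 0.105). The median neutrophil marker was 4.79 above control gilts in gilt 47 and between 0.50 and 3.41 in the hormone horns of the others. Of the 7 lists that passed, cell division and glycolysis did so whichever gilt was left out. The secretory list did not without gilt 14, 38, 40, 41 or 46, and endothelial markers did not without 9, 14, 38, 40 or 41. Macrophage markers did not pass without gilt 9, 38, 41 or 46 or with no gilt block, the chaperones without 41 and the matrix without 9 or 38. Of these 7 lists, 4 passed with quantile normalization (not the secretory, matrix and endothelial lists), 3 with normexp (nor the chaperones). Only cell division of the 7 passed with slide or the annotation class difference as a term. In all, 19 of the 26 tested lists did not pass with cameraPR, which sets a list against the other genes. With fry, which tests a list on its own against no change, 13 lists passed, including neutrophil markers (adjusted p = 0.00277) but not macrophage markers. All list members are probes identified by RefSeq, a class with a median of 0.199 in hormone horns. A test against no change therefore leans towards a rise here.

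LPAR3, a lysophosphatidic acid receptor regulated by estrogen in the pig uterus, rose by 2.73 ± 0.46 (6.62-fold, adjusted p = 0.00264). AKR1B1, an aldo-keto reductase with prostaglandin F synthase activity, rose by 2.05 (adjusted p = 0.0184; it did not pass without gilt 9, 14 or 28), and PTGR1, which acts on prostaglandin metabolites, rose by 1.68 ± 0.27 (adjusted p = 0.00238). HSD11B1, an enzyme of glucocorticoid metabolism, rose by 1.48 and the VEGF receptor FLT1 by 1.30. The growth factor EGF fell (-2.04 ± 0.46, adjusted p = 0.0106). The prostaglandin list as a whole did not pass (3 of 11 higher, adjusted p = 0.172), nor did the estrogen-responsive list (4 of 19 higher, adjusted p = 0.128). With fry both did (adjusted p = 0.000467 and 0.000468), a test that leans towards a rise here because RefSeq probes as a class were higher. SPP1, which encodes an adhesive protein of the uterine surface, had 2.82 ± 0.98 (adjusted p = 0.0668) and ESR1, the estrogen receptor gene, -0.59 ± 0.20 (adjusted p = 0.0665), so neither passed. PGR (0.33), PTGS2 (0.41), PTGES (0.13), VEGFA (0.37), STC1 (1.29) and SLC5A1 (-0.38) did not pass either (adjusted p from 0.359 to 0.825).

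**Figure D2:**
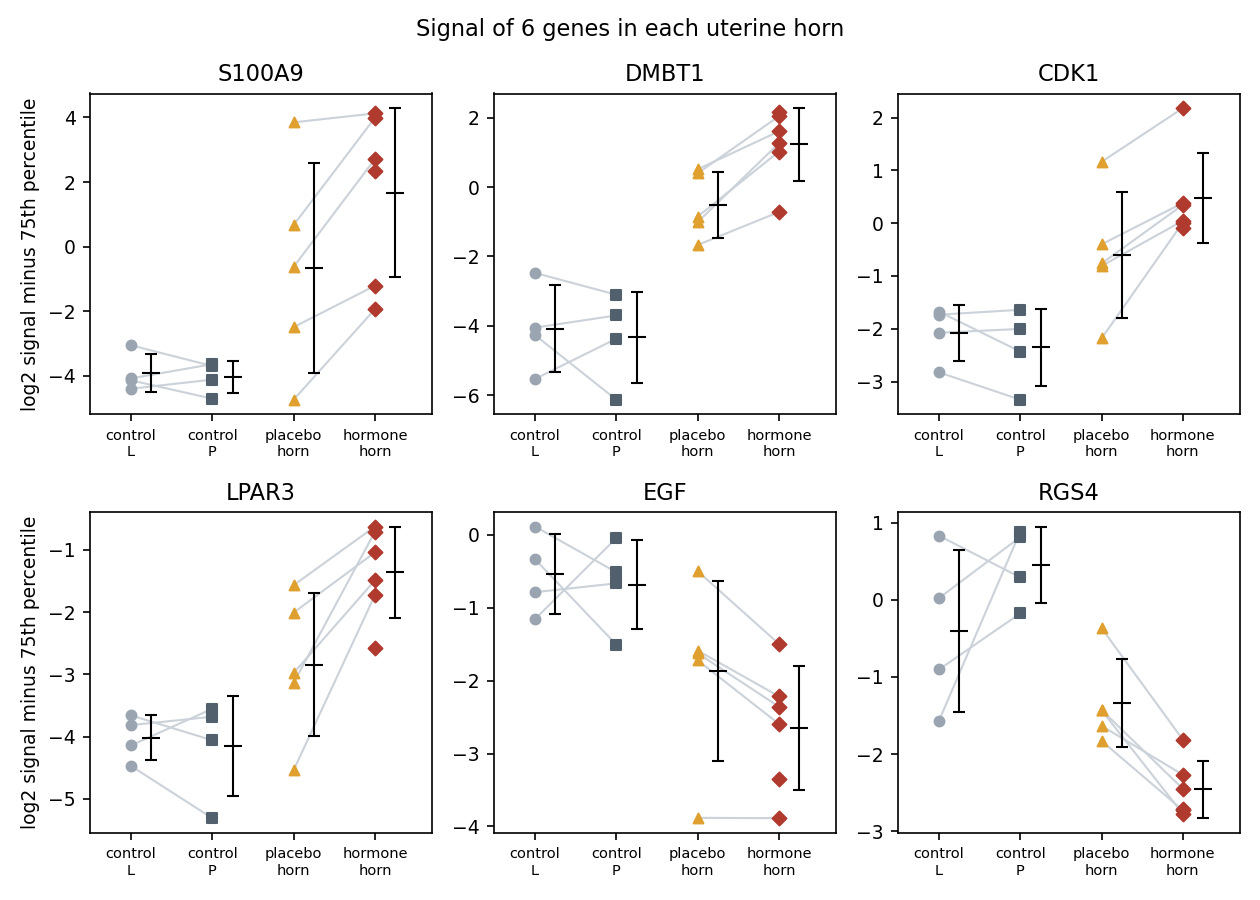
Log2 signal minus the array's 75th percentile for 6 genes in control horns marked L and P (4 gilts), placebo horns (n = 5) and hormone horns (n = 6) of treated gilts, 1 point per horn, lines joining the horns of a gilt, with mean ± SD beside each group. CDK1 averages -2.22 in control gilts, -0.60 in placebo horns and 0.48 in hormone horns, and EGF and RGS4 descend in the same order.

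The placebo horn of treated gilts was set against control gilts to see whether a horn that received no hormone differed from animals that received none at all. Many of the same genes were raised there. S100A8 rose by 4.34 ± 1.19 log2 units (adjusted p = 0.0454), SAA3 by 4.32 ± 1.02 (adjusted p = 0.0311) and DMBT1 by 3.78 ± 0.61 (13.7-fold, adjusted p = 0.00954; 5 placebo horns against 8 control horns). CHI3L1, FCN1, SLC15A1, LYZ, TMEM171, ADM and UPK1B rose by 3.54, 2.76, 2.76, 2.67, 2.32, 2.04 and 1.95. REG3G fell by 2.75 and the troponin gene TNNT1 by 2.14, followed by CBR2 (-2.01), DIRAS2 (-1.70), CDC25C (-1.31), the Wnt antagonist SFRP4 (-1.27), SLC25A27 (-1.24), GAP43 (-1.23), PLCD4 (-1.09) and the transcription factor MITF (-1.02). HIF1A, a transcription factor of the response to low oxygen, rose by 1.01 (adjusted p = 0.0339). CEBPB, a transcription factor, rose by 1.93 in placebo horns (adjusted p = 0.00917) and by 1.79 in hormone horns (adjusted p = 0.00242).

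Macrophage and dendritic cell markers shifted upward in placebo horns (1 of 13 passing, 5 adjusted over the list alone; median 0.91; adjusted p = 0.000996), with gilt 47 at 2.72 and the others at 0.17 to 1.19. The lists of cell division (1 of 9 passing, 7 adjusted over the list alone; median 0.65; adjusted p = 0.00319), endoplasmic reticulum chaperones (3 of 11; 5 adjusted over the list alone; adjusted p = 0.005), oxygen lack and glycolysis (1 of 7; 5 adjusted over the list alone; adjusted p = 0.00926) and secretory products (1 of 19; 3 adjusted over the list alone; adjusted p = 0.0457) shifted upward too. For cell division the median above control gilts was 1.95 in gilt 47, 0.0555 in gilt 44 and 0.411 to 0.852 in the other gilts. The secretory list did not pass without gilt 14, 38, 40, 41 or 47 or with no gilt block. With slide as a term only the cell division list still passed, and with the annotation class difference as a term none of the 5 did. With fry 13 lists passed, among them these 5, but RefSeq probes as a class had a median of 0.125 in placebo horns. None of these 5 lists passed with an estimated correlation (adjusted p = 0.42 with an estimated correlation for each). In total 1754 probes passed (limma), 1000 higher and 754 lower. This count was fragile: it was 0, 4, 139, 414, 419 and 931 without gilt 28, 14, 9, 38, 47 and 41, 3211 without gilt 36, 14 with only these groups in the fit, 20 with the horn mark as a term (all placebo horns are marked L), 0 (8677 at an unadjusted p under 0.05) with the horns of each control gilt averaged and no block, 3567 without the block, 409 without gilt 47 and the hormone horn of gilt 36, and 2205 with scan day as a term (9, 7 and 0 within the scan days, which held 1 or 2 gilts per group). With the horns of each control gilt averaged and no block, the smallest limma adjusted p over all probes was 0.0768, so no gene named here passed. None of the 24 named genes that had passed with the block did so whichever gilt was left out. All 24 kept their direction, a weak check, since 20 of them were taken as the largest differences in the same arrays.

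Of the probes that passed in placebo horns, 879 of the 1000 higher ones also passed as higher in hormone horns (68.6 for independent lists of these sizes), as did 658 of the 754 lower ones (36.9 for independent lists), with 0 in opposite directions. Both comparisons share the control arrays and 5 gilts. The log2 differences of the 2 kinds of horn from control gilts correlated at 0.879 across 38533 probes, which are not independent replicates. Simulated unchanged groups with the same gilts and controls gave 0.751. The covariance was 0.257, against 0.0794 in the simulation. The simulation drew each probe independently with the same correlation within gilts, whereas the real probes vary together. Its narrow range (correlation 0.741 to 0.761) therefore understates the spread of unchanged groups, and whether the real values exceed that spread was not tested. With control gilts split so that the 2 comparisons shared none, the correlation was 0.692 (covariance 0.223). With disjoint treated gilts as well it averaged 0.502 (range 0.288 to 0.659), and the covariance averaged 0.192 (range 0.0963 to 0.306).

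The contrast of the hormone horn with the placebo horn of the same gilt drew mainly on the 5 gilts with both horns, while the hormone horn of gilt 40, which has no partner, also entered through the random block. With the gilt as a fixed block, which compares horns only within a gilt, 5 of the 8 lists below still passed, and those of the matrix, the stroma and T and natural killer cells did not. Cell division genes had the smallest adjusted p of the 26 lists. All 9 measured members had positive values, with a median of 0.76 log2 units (cameraPR adjusted p = 4.4e-05; adjusted p = 0.212 with an estimated correlation), and 6 of 9 passed when adjusted over the list alone. CDK1 was at 1.14 ± 0.30 and CCNB1 at 0.76 ± 0.21, and neither passed over all probes (limma adjusted p = 0.227 and 0.258). List members such as these and PTGR1 were named for their small p in this comparison. The list's difference between horns was 0.481 to 0.935 in the 5 treated gilts and -0.302 to 0.103 in the 4 control gilts (exact permutation p = 0.00794, the smallest that 126 splits can give, and 0.206 adjusted over 26 lists). The largest value among the genes of interest was LPAR3 at 1.62 ± 0.32 (adjusted p = 0.0989), followed by AKR1B1 at 0.93 ± 0.37 (adjusted p = 0.424). PTGR1 was at 0.94 ± 0.19 (adjusted p = 0.105). BAALC (-1.44, adjusted p = 0.152), DEFB1 (-1.52, adjusted p = 0.212) and RGS4 (-1.09, adjusted p = 0.213), named for their falls in the same hormone horns, did not pass.

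Genes of the response to cAMP, a second messenger of some PGE2 receptors, were lower in the hormone horn than in the placebo horn. All 10 measured members were negative (median -0.16, adjusted p = 0.00659; adjusted p = 0.119 with an estimated correlation; 0 passed adjusted over the list alone), with AREG at -1.16 and NR4A2 at -0.72, and the shift did not pass without gilt 41. The median horn difference was -0.902 in gilt 41 and 0.0921 in gilt 38. Against control gilts the list's median was positive in all treated horns except those of gilt 36, so the genes were mostly not below control gilts. Cytokines and chemokines shifted downward (23 of 30 negative, median -0.15, adjusted p = 0.000577; adjusted p = 0.304 with an estimated correlation; 0 adjusted over the list alone), with IL1A at -1.02. Their median in hormone horns was also above control gilts except in gilt 36. Interferon response genes did as well (median -0.12, adjusted p = 0.00659; adjusted p = 0.844 with an estimated correlation), but not without the hormone horn of gilt 36, and the horn difference averaged -0.0635 in treated and -0.114 in control gilts (exact permutation p = 0.802). Extracellular matrix genes (median 0.24, adjusted p = 0.0489; 5 of 14 adjusted over the list alone) and stromal fibroblast markers (median 0.25, adjusted p = 0.0249; 3 of 5 adjusted over the list alone) shifted upward and T and natural killer cell markers downward (median -0.14, adjusted p = 0.049; mean horn difference -0.0632 in treated and -0.0307 in control gilts, exact permutation p = 0.81), with adjusted p = 0.721, 0.522 and 0.721 with an estimated correlation. For cAMP response, cytokines, matrix and stroma the horn differences of treated and control gilts gave exact permutation p = 0.19, 0.175, 0.119 and 0.357. The matrix and T cell shifts ended under most other settings, and those of the matrix and the stroma without gilt 38, 44 or 47. Of the 8 lists that passed between horns, including smooth muscle, only cell division, cAMP response and cytokines passed once the P over L difference of control gilts was subtracted. The same 3 and interferon response passed with slide as a term. Neither cAMP response, cytokines nor interferon response passed without gilt 47 and the hormone horn of gilt 36. With fry 3 lists passed between horns, namely cell division, stromal fibroblasts and the prostaglandin list (adjusted p = 0.0475 each). Smooth muscle markers of the myometrium, the muscle wall, were higher in the hormone horn (median 0.66, adjusted p = 0.0249; adjusted p = 0.721 with an estimated correlation), with horn differences of 0.299 to 1.46 in the 5 treated gilts. In control gilts the P minus L differences were 3.18, 0.671, -0.074 and -0.729.

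Over all probes, limma called 1 between the horns of a gilt, a probe with no gene symbol here (A_72_P705429, 1.41 ± 0.195, adjusted p = 0.0343), chosen after its value was seen. At an unadjusted p under 0.05 there were 3839 probes (9.83%), a share that is not evidence of change, since 9 of 32 ways of swapping horns within gilts (the real one included) gave at least the real number in a simpler fit. The count was 0 to 15 with 1 gilt left out, 0 with the gilt as a fixed block or with no block, 34 with quantile normalization, and 0 (1278 at an unadjusted p under 0.05) once the P over L difference of control gilts was subtracted. Within the scan days it was 4235, 0 and 4, but days 1 and 3 held 2 pairs each, on day 1 including gilt 36, and day 2 held a single placebo horn, assumed to vary like the other group.

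**Figure D3:**
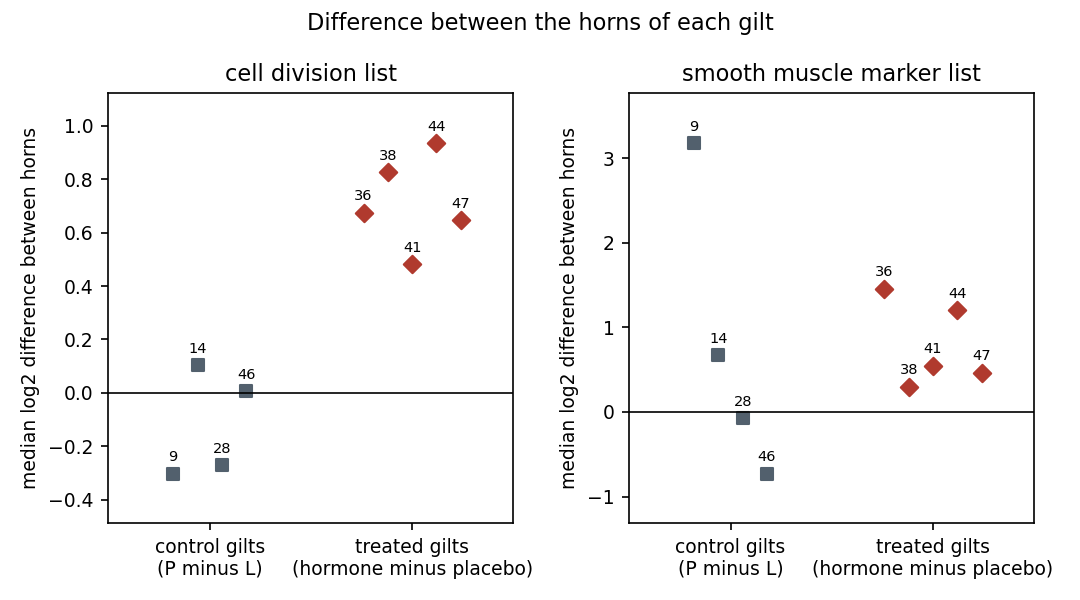
Median log2 difference between the horns of each gilt over the cell division list (left) and the smooth muscle marker list (right), as P minus L in 4 control gilts and hormone minus placebo in 5 treated gilts, 1 point per gilt. For cell division the treated gilts lie at 0.481 to 0.935, above all control gilts (at most 0.103), while for smooth muscle control gilt 9 has the highest value, 3.18.

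Within control gilts, horns marked P and L served as the background for the contrast between horns. No cell division gene or any other named gene passed, and limma called 0 of 39072 probes (942, or 2.41%, at an unadjusted p under 0.05). Smooth muscle markers were the only list that passed: all 6 members were higher in horns marked P (median 0.77, adjusted p = 1.88e-06; adjusted p = 0.507 with an estimated correlation), with CNN1, a smooth muscle calponin, at 1.12 and ACTA2 at 0.47, 0 passing adjusted over the list alone. This shift came from gilt 9, whose horns differed by 3.18, and the median was -0.04 without that gilt. The mean difference between horns in smooth muscle markers was 0.794 in treated gilts, positive in 5 of 5, and 0.762 in control gilts, positive in 2 of 4 and carried by gilt 9, so the exact permutation p of 0.976 does not show that the groups were alike.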

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

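The permutation of list differences between horns, the scan day, gilt 47 and brightness tests, the split of horns by unadjusted p, and the comparison of gilt 36 with control gilt 9 were chosen only after the results they concern had been seen. So was the test of RefSeq against contig probes, which used the same arrays. The split by unadjusted p was added because the number of called probes was 0 in every split.

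Among 452 sets of a named gene in a group of arrays, 39 had 1 array far from the others by Dixon's criterion, where chance alone gives about 1 in 20 (22.6). Of these, 13 were in gilt 47, 5 in the hormone horn of gilt 36 and 18 in control gilts. Each value below is the log2 signal of that array minus the mean of the others of its group.

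In gilt 47 the hormone horn stood apart for SERPINA3-2 (5.18), LYZ (3.04), CDK1 (2.04), CCNB1 (1.87), KLRK1 (2.8), AIF1 (2.71) and CD79A (2.38), and the placebo horn for SERPINA3-2 (7.23), RGS4 (1.21), PGK1 (0.799), SPAG6 (-2.22), CD79A (2.41) and MS4A1 (3.34). The hormone horn of gilt 36 stood apart for PGR (0.746), PLET1 (2.79), SLC34A2 (0.949), HSPB1 (0.711) and HSPA8 (0.449). Among other treated gilts this held for CELA2A in the placebo horn of gilt 38 (1.84), NR4A2 in the hormone horn of gilt 38 (2.70) and TMEM171 in the hormone horn of gilt 41 (-1.25).

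In control gilt 9 the horn marked P stood apart for LYZ (-1.50), ITIH4 (-0.879), ITGB5 (-0.441), CLDN8 (-1.64), CXCL16 (-1.70) and PTGS2 (-1.53), and the horn marked L for LYZ (-0.464) and SLC25A27 (-0.539). In control gilt 46 the horn marked P stood apart for REG3G (0.683), PGK1 (0.269) and DCN (-0.252), and the horn marked L for SFRP4 (1.02), NR4A2 (0.521), ATP2B1 (0.200), PGK1 (0.105) and GLI1 (0.306). The horn marked L of gilt 28 did so for GDF15 (0.334), and the horn marked P of gilt 14 for TMEM171 (0.973).

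The difference between horns differed between treated gilts (hormone minus placebo, n = 5) and control gilts (P minus L, n = 4) for 2 of 26 lists at an unadjusted exact permutation p under 0.05. For cell division the means were 0.713 and -0.116 (exact permutation p = 0.00794, 0.206 adjusted over lists). For neutrophil markers they were 0.504 and -0.148 (exact permutation p = 0.0397, 0.413 adjusted over lists).

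The groupings were tested in a simpler fit than elsewhere: 2 groups on the arrays compared, control horns marked L and P pooled, the 38533 probes with a value on every array, and the correlation within gilts estimated from a random subset of probes, so the real counts differ from those of the other fits. Hormone horns against control gilts had 3145 called probes and the most in any other of the 100 groupings tried was 946, so only 1 grouping, the real one, reached that count. Control gilts brought 2 arrays each and treated gilts 1, so every other grouping had different numbers of arrays per group. Its count is therefore not fully comparable with the real one, which also holds for the placebo horns. For placebo horns against control gilts, likewise only 1 of 100 reached the real count, but the counts were 4 called probes against at most 3, and with L and P as separate groups over all tested probes the real count was 14, so this test carries little weight. Between the horns of treated gilts, 32 of 32 splits had as many called probes as the real one, since all had 0. By unadjusted p, 9 of 32 splits had at least the real number (2348; highest 6505, median 1031), so the number of probes with small p between horns does not stand out from arbitrary swaps of horns. In control gilts 8 of 8 splits matched, with 0 called probes each, and 8 splits cannot reach a p under 0.05.

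The first pattern weighed was that both horns of treated gilts differed from control gilts. A difference between scan days could not account for it, because 5102 probes passed in hormone horns and 2205 in placebo horns with scan day as a term. The counts did depend on the arrays of single days. Without scan day 2, which held 2 of the 4 control gilts, 3 probes passed in hormone horns and 0 in placebo horns. Without day 3 these counts were 3751 and 1, and without day 1 they were 2736 and 3122. Gilt 47 alone could not account for the hormone horns, where 4864 passed without it, but in placebo horns the count fell from 1754 to 419, so its part there is left open. A biological account, hormone action in both horns that was stronger in the infused one, predicts that horn differences follow the difference from control gilts. The mean slope was 0.0791 in treated and -0.0351 in control gilts (exact permutation p = 0.413), which leaves this open, as it leaves open a difference between the groups of gilts that preceded the infusions. Slides could not be separated from gilts either, since 8 of the 9 slides held the arrays of 1 gilt each.

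The second pattern was that probes identified by RefSeq tended to be higher, and those identified by contigs lower, in treated gilts. The class difference per gilt was 0.119 ± 0.0808 in treated and -0.178 ± 0.0516 in control gilts (mean ± SD). The exact permutation p was 0.00476, the smallest that 210 splits can give. Probe brightness alone could not account for it, since RefSeq probes exceeded contig probes by at least 0.0957 in each of 5 brightness classes (hormone horns against control gilts). The gap did vary with brightness, from 0.0957 in the dimmest class to 0.411 in class 4, and contig probes were not lower in the dimmest class (0.0486). A part for brightness is therefore not excluded. Every treated gilt (lowest 0.0308) lay above every control gilt (highest -0.103), so neither gilt 47 alone nor scan day could account for the pattern. Given that order, leaving out gilt 47 could only give the smallest p that 126 splits allow (exact permutation p = 0.00794). The gap between treated and control gilts of a scan day could likewise only be positive (smallest 0.134), so neither is a separate test. Hormone horns exceeded placebo horns in 3 of 5 pairs (0.0306 ± 0.135, mean ± SD). Whether RNA quality or biology underlies the difference between gilts was not tested, because no RNA quality value per sample was held.

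The third pattern was the hormone horn of gilt 36. An intensity-dependent effect of a weak array would shrink under quantile normalization, but the horns still differed by 0.777 (root mean square log2; at most 0.540 in other gilts). Less epithelium would lower epithelial markers, which were 0.183 higher. More myometrium predicts higher smooth muscle markers, a prediction written before the value was seen, and the difference of 1.46 was the highest of the treated gilts. Control gilt 9 had 3.18 although the distance between its horns (0.514) was not unusual, a comparison made afterwards, and the account is left open.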

How the results depend on the processing

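The scan day term, normexp on median signals, the annotation class term, the fits without the hormone horn of gilt 36 (alone or with gilt 47) and the use of the fitted differences for the resemblance under added terms were chosen after the data were seen. Normexp on mean signals was not run, since that column was not held. Where a value moved, the cause was not tested unless stated. Of the counts of called probes 67 stayed within 1.5 times and 46 did not. The 67 include every fit of P against L in control gilts, where the count was 0 throughout. They therefore overstate the stability of the comparisons that had calls. Of the values of named genes 8885 kept direction and side of the threshold, 513 lost and 163 gained a call, and 2 reversed. For lists the numbers were 2812, 152, 72 and 6.

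Between the horns of treated gilts (1 called probe) the count was 0 with no block and with the gilt as a fixed block, 0 with median scaling, the authors' table, probes well above background on all arrays, the horn mark as a term and the horn-corrected contrast, 34 with quantile normalization, 20 with normexp, 16 with slide and 4 with scan day as a term, 4 without the hormone horn of gilt 36, 21 also without gilt 47, 8 with the class term, and 0 to 15 with 1 gilt left out. The fixed block also ended the stromal, matrix and T and natural killer cell list calls between horns and the smooth muscle call in control gilts, and changed no other call there.

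For hormone horns against control gilts (4591) the count was 6965 without the block, 2525 on means of control horns, 0 with the class term, and 1465 to 5241 with 1 gilt left out. For placebo horns against control gilts (1754) it was 3567 without the block, 0 on means of control horns, 14 with only the groups compared, 1012 with normexp, 20 with the horn mark, 3168 with slide, 2795 with array weights, 409 without gilt 47 and the hormone horn of gilt 36, 0 with the class term, and 0 to 3211 with 1 gilt left out. Slide as a term leaves treated against control gilts to the 2 gilts of 1 slide. In control gilts P against L was 0 in every fit.

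The resemblance of the horns was 0.852 with the horn mark and 0.933 with slide, against 0.887 for the fitted differences. It was 0.814 without gilt 47 and the hormone horn of gilt 36 and 0.502 with disjoint gilts, against 0.879, and 0.809 to 0.897 with 1 gilt left out.

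Some directions reversed. For the marker: smooth muscle of the myometrium, hormone horn against contralateral placebo horn, the median was 0.66, but 0.10 with the horn mark as a term and 0.0158 horn-corrected, where the tested direction reversed. For the marker: smooth muscle of the myometrium, horn P against horn L in control gilts, it ranged from -0.0392 to 1.27 with 1 gilt left out. For uterine secretory products and protease inhibitors, hormone horn against control gilts, and for uterine secretory products and protease inhibitors, contralateral placebo horn against control gilts, the tested direction reversed with slide as a term, because members lay below other genes although their medians were 0.46 and 0.30. With the class term the marker: macrophages and dendritic cells, hormone horn against control gilts, had a median of -0.205, CBR2, hormone horn against control gilts, had 0.27, and ENG, hormone horn against control gilts, had -0.0269. No list call held with an estimated correlation. With fry 3 lists passed between horns (against 8), 13 in hormone horns (against 7), 13 in placebo horns (against 5) and 0 in control gilts (against 1). Without the filter on signal over background, 1, 4543 and 1649 probes passed between horns and in hormone and placebo horns against control gilts.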

Other observations

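These genes were picked out here after their values were seen, from lists that did not pass in hormone horns against control gilts or, for SPAG6, were not tested. Apart from MUC4 and SGK1 they were also named by the rule fixed beforehand. In hormone horns against control gilts, genes of the uterine surface and of the epithelium were among those that rose (adjusted p from limma). MUC4, a membrane mucin, was 2.28 log2 units higher (adjusted p = 0.0106), and CLDN4, a tight junction protein, 1.36 higher (adjusted p = 0.0143) and 1.53 higher in placebo horns (adjusted p = 0.0252). EPCAM, an epithelial adhesion protein, was 0.69 higher in hormone horns (adjusted p = 0.00239) and 0.57 higher in placebo horns (adjusted p = 0.0214). The adhesion list had 5 of 22 members higher and did not pass (adjusted p = 0.212), nor did the epithelial list (3 of 8, adjusted p = 0.186).

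Among stress and signalling genes, the chaperone HSPA8 was 0.78 higher in hormone horns (adjusted p = 0.00379) and the kinase SGK1 was 1.72 higher (adjusted p = 0.00286). GZMB, a protease of cytotoxic lymphocytes, was lower (-0.93, adjusted p = 0.0106), but did not pass without gilt 28, on means of control horns without the block, or with the annotation class term. The ciliated cell list had 1 measured gene and was not tested: SPAG6 was at -0.25 in hormone horns against control gilts.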
